A study of Caenorhabditis elegans with 2 samples.

How the data were processed

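Chromatin immunoprecipitation sequencing (ChIP-seq) recovers the DNA bound to a chosen protein, sequences it and calls the places where reads pile up as peaks. Here the protein was ZIP-5, a basic leucine zipper (bZIP) transcription factor of the nematode Caenorhabditis elegans, expressed from a transgene as a fusion to enhanced green fluorescent protein (eGFP). It was recovered with an antibody against GFP from late embryos collected 4 hours after synchronization, in which gravid animals are bleached to release their eggs. Per the labels, 2 biological replicates form the only group, so there was no comparison between groups, and each statement on the group rests on 2 libraries.

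The authors deposited 4 kinds of peak list in each of 2 genome builds, ce10 and ce11. Per the file listings deposited with the samples, 1 list was called on the alignment of each replicate with a control, and a further list on both alignments together with a control. These 3 are relaxed lists that hold peaks and background as input for the irreproducible discovery rate (IDR), a measure of how well the ranks of peaks agree between replicates. The optimal IDR set was derived from those 3 lists. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here, and the control libraries were not used here. The signal value that the authors' lists give for each peak is a peak score with no stated scale, so it was used only to rank, describe or compare peaks within a list, or as a correlation between lists (by rank, and by Pearson's r of log10 signal). The deposited lists also give a −log10 q-value per peak, and 66.1% of the optimal ce11 peaks shared its highest value, so it was used only to break ties. Summits are the point sources in the lists. Most peaks have the same width within a list (444 bp for 85.0% of the optimal ce11 set), so widths carry little information on the size of the bound region. The lists carry no read counts, and the sequencing depth is unknown. Exact intervals below therefore cover the counting of peaks or genes only.

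The ce11 lists were the main data because a genome of the same coordinates (WBcel235) and the Ensembl 115 annotation were at hand. All optimal ce11 peaks ended inside its chromosomes. No coordinate was converted between builds. Location, gene lists, sites and words were computed on the 730 optimal peaks of the 6 nuclear chromosomes, a restriction the plan had not stated, and the 16 mitochondrial peaks are reported apart. Coordinates are counted from 1.

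Overlap meant at least 1 shared bp. Overlaps and locations were compared with 1000 circular shifts of the peaks within each chromosome, whose smallest p is 0.001 one-sided and 0.002 two-sided. A promoter window ran from 1000 bp upstream to 200 bp downstream of the outermost annotated start of a protein-coding gene. Many nematode genes are trans-spliced, so an annotated start need not be a transcription start. Summits outside these windows were assigned to exons, introns or intergenic sequence of protein-coding genes, in that order. Gene lists (25 of protein-coding genes and 3 of RNA genes) were tested with Fisher's exact test, two-sided, against all other genes of the nuclear chromosomes, which were protein-coding for the first kind and of all biotypes for the second. Benjamini-Hochberg adjustment was made within each kind. The names atf-5 and daf-21 had no match in the annotation. The 25 lists covered ribosomal proteins, histones, collagens, bZIP factors, homeobox genes, nuclear hormone receptors, bHLH factors, intestine, epidermis, muscle, pharynx, neurons, germline, folate, endoplasmic reticulum stress, mitochondrial stress, chaperones, oxidative and xenobiotic defence, immune effectors, neuropeptides and insulins, lipid metabolism, Wnt and Notch, cell cycle, proteasome, and vacuolar ATPase with lysosome and autophagy. The 19 fixed sites were counted within 100 bp of the summit and in a window of the same size centred 500 bp away, on a side drawn at random with a fixed seed, with an exact two-sided McNemar test. Sides were drawn again for the promoter peaks, the other peaks and the set without tRNA and snoRNA peaks. A peak can therefore have another control window there than in the full set. The paired ratio of a site is the number of peaks with it at the summit alone over the number with it in the control window alone, 0.5 added to each, so it is not the ratio of the 2 shares and depends on the added 0.5 where a number is 0. All 6-mers and 8-mers, a word and its reverse complement counted as 1, were compared with both flanking windows by Fisher's exact test and adjusted within each length. Correlations and differences of medians used 100000 permutations, and the distribution over chromosomes the same number of random draws. Shares carry exact Clopper-Pearson 95% intervals. Genes and peaks are not replicates, and p-values over them describe these lists, not the variation between animals.

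The named genes were fixed before the data were examined, as were the tests, the gene lists, the sites and most alternatives. They are zip-5 and unc-119, the genes at the 20 strongest optimal peaks, the 4 members with the strongest peak in each gene list past the threshold and in the bZIP, folate and endoplasmic reticulum stress lists, and the 5 promoter windows with the strongest peak held by both replicate lists but not by the optimal set. Genes named outside this rule were chosen after their values were seen and are marked so.

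The alternatives were other rules of overlap, the stronger 50% of the optimal set, the 746 strongest peaks of 1 replicate list in place of the optimal set (leaving out the other replicate), the ce10 lists, other promoter windows, the nearest start, a background matched on the distance to the next gene upstream, clustered list genes counted once, other windows and controls for sites, and sets without tRNA and snoRNA peaks. The tests of location, overlap, gene lists, fixed sites and 8-mers were tried on simulated data, and the others were not. Of 20 simulated sets of peaks placed at random, 1 gave a location class past the threshold, and of 20 independent lists 2 gave an overlap past it. With bound genes drawn at random, 1 of 100 sets gave any gene list, and a planted list of 80 genes with 7 times the odds was found in 100 of 100. Smaller planted lists and weaker effects were not simulated. The genes were drawn singly, whereas a summit can lie in the windows of several genes. Random summits gave 0 sets of 10 with a fixed site past the threshold, and 0 8-mers over 3 sets. These summits were placed evenly over the genome. Calls that come from a difference in composition or location between summits and flanks were therefore not simulated. A planted word ranked first in 3 of 3 sets. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and BLAST 2.17.0 for copies of summit windows.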

Results

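ChIP-seq of ZIP-5-eGFP was carried out on late embryos in 2 biological replicates of 1 group. The replicate 1 list held 6253 peaks and background regions and the replicate 2 list 6945, and 4380 were called on both alignments together. The optimal IDR set held 746 peaks, 730 on the nuclear chromosomes and 16 on the mitochondrial chromosome, with signal values from 95.2 to 2499 and a median of 161.1. All 746 were entries of the list called on both alignments, and no entry of that list as strong as the weakest optimal peak was left out of the set. The ce10 lists held 722 optimal peaks (708 nuclear and 14 mitochondrial), 4373 called on both alignments, 6225 for replicate 1 and 7212 for replicate 2, with a median optimal signal of 164.5. Chosen only after data were seen were the overlap of the strongest peaks of both replicates, the distances and shared windows of promoter summits, the summits within 100 bp of RNA genes, the joint count of bZIP sites, and the words by class of peak.

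The first question was how far both libraries gave the same peaks. At the top of the lists they shared most of them, and further down they shared few. Loci that any immunoprecipitation recovers would be shared too, and none without the tag was used here. Shared peaks, their locations and their genes therefore need not reflect binding of ZIP-5. The strongest peak, upstream of K12H4.5, ranked first in both replicate lists. Of the 746 strongest peaks of replicate 1, 618 (82.8%, 95% interval 79.9 to 85.5) overlapped one of the 746 strongest of replicate 2. In the other direction 604 (81.0%, 78.0 to 83.7) overlapped, against means of 2.59% and 2.48% over the shifts. Of the full lists, 41.1% of replicate 1 peaks (39.8 to 42.3) and 36.7% of replicate 2 peaks (35.6 to 37.8) overlapped a peak of the other list, against 6.35% and 5.68% over the shifts. The shared part fell from 86.2% in the strongest 20% of the replicate 1 list to 20.9% in the weakest 20%, and from 82.2% to 18.4% in the replicate 2 list. Of the optimal set, 745 peaks (99.9%, 99.3 to 100) overlapped the replicate 1 list and 746 (100%, 99.5 to 100) the replicate 2 list, which is not independent evidence because the set was derived from these lists. All these overlaps exceeded every shift (one-sided permutation p = 0.001, the smallest the shifts can give). Across the 745 optimal peaks with a match in both lists, log10 signal correlated with Pearson's r = 0.871 and Spearman's rho = 0.820 (permutation p = 1e-05 for each, the smallest the permutations can give). Peaks are not independent replicates. The optimal set was also derived from these lists with a measure of rank agreement, so the correlation and its p are not independent evidence.

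**Figure D1:**
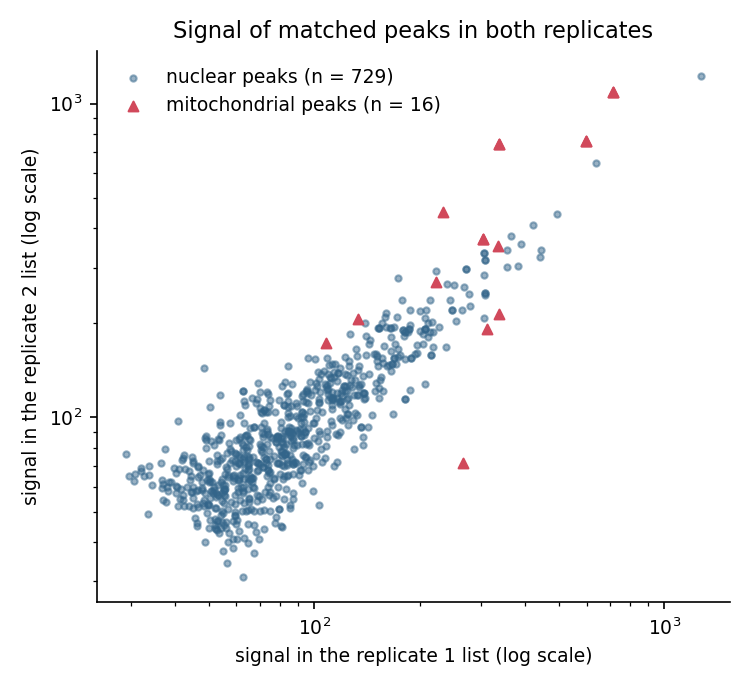
Each point is 1 of the 745 optimal peaks with a match in both replicate lists, plotted by the signal of its strongest overlapping peak in the replicate 1 list (x axis) and the replicate 2 list (y axis), both on log scales, with nuclear peaks as circles and the 16 mitochondrial peaks as triangles. The signals rise together (Spearman's rho = 0.820), and the strongest nuclear peak lies at 1272 and 1227. The peaks were selected by IDR from these lists, so their agreement is not independent evidence.

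ZIP-5-eGFP peaks lay mainly just upstream of protein-coding genes. Of the 730 nuclear summits, 457 (62.6%, 59.0 to 66.1) fell in a promoter window, against 21.4% over the shifts, a ratio of 2.92. Introns held 161 summits (22.1% against 31.2%), intergenic sequence 103 (14.1% against 24.1%) and exons 9 (1.23% against 23.3%). Each share lay outside the range of the shifts (two-sided adjusted permutation p = 0.002 for each, the smallest they can give). The intergenic share was 21.2% with a window of 500 bp upstream and 8.39% without the peaks at tRNA and snoRNA genes, and the exon share 1.92% without replicate 1 and 2.07% without replicate 2, all still below the shifts. The promoter summits had a median position of -201 bp from the nearest start, and 282 of them (61.7%) lay within 250 bp of a start. Windows of genes on both strands held 203 of the 457 promoter summits (44.4%, 39.8 to 49.1), although such shared sequence made up 9.73% of all promoter bases. The latter share was taken over whole windows and not at the distances of the summits, so the comparison is not matched on position. In all, 664 of 19973 protein-coding genes (3.32%) had a summit in their window. Promoter peaks were also the stronger ones, with a median signal of 167.8 against 139.6 for the other 273 nuclear peaks (two-sided permutation p = 2e-05).

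**Figure D2:**
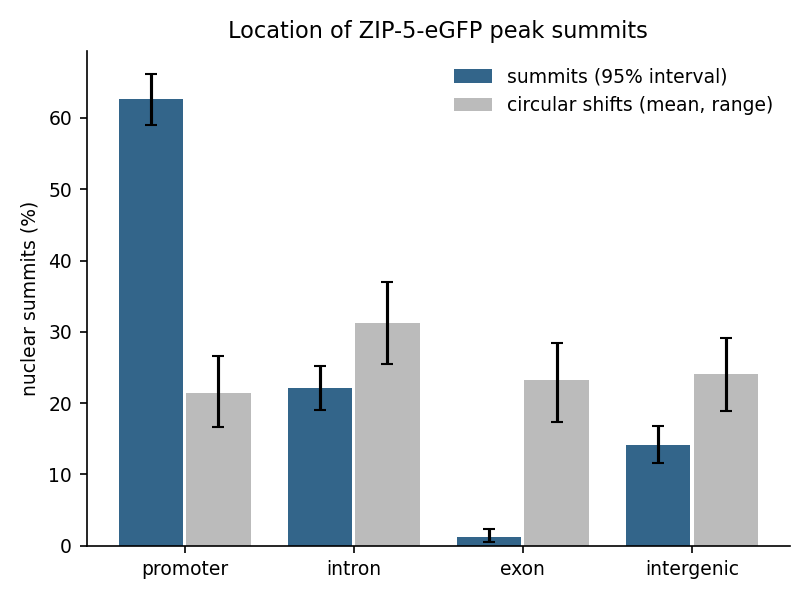
Percent of the 730 nuclear summits in promoter windows, introns, exons and intergenic sequence (dark bars, with exact 95% intervals), beside the mean of 1000 circular shifts (grey bars, with the range of the shifts). Promoter windows hold 62.6% of the summits against 21.4% over the shifts, and exons 1.23% against 23.3%.

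Of the 20 strongest optimal peaks, 12 had a summit in a promoter window, 7 of these in the windows of a pair of genes, 7 were mitochondrial and 1 lay in a snoRNA gene. The strongest peak (chromosome III, 8043709 to 8044211, signal 2499) had its summit at -531 bp from the start of K12H4.5, with a signal of 1272 in the replicate 1 list and 1227 in the replicate 2 list. The peak near M01F1.9 followed among nuclear peaks (III, 3499784 to 3500255, signal 1271), with its summit at -968 bp from that gene's start and in an intron of M01F1.8. A peak with signal 934.9 (IV, 17087328 to 17087777) lay between snr-1, which encodes a core protein of the spliceosomal small nuclear ribonucleoproteins, and snx-13, which encodes a sorting nexin. The peak upstream of chaf-2, a chromatin assembly factor subunit, and of Y71G12B.30 had a signal of 830.4 (I, 1822997 to 1823405), with the summit at -249 and -250 bp. The region between jmjd-1.2, a histone demethylase gene, and F29B9.11 held a peak of 744.1 (IV, 4660454 to 4660839). Between lin-35, the nematode homologue of the retinoblastoma tumour suppressor, and vps-51, a gene of vesicle tethering, the signal was 696.2 (I, 5807258 to 5807666), with the summit at -265 and -153 bp. Other peaks of this group lay upstream of Y41D4A.4 and Y41D4A.6 (784.6), Y50D4C.5 (762.7), W03H9.2 (742.3), C34C12.9 (683.4), tag-267 and tag-266 (658.1), and Y92H12BR.2 and Y92H12BR.3 (618.7).

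The gene lists asked whether promoter peaks fell on particular kinds of gene. Among the 25 lists of protein-coding genes, only that of ribosomal proteins passed the threshold. Of its 81 genes, 16 (19.8%, 11.7 to 30.1) had a summit in the promoter window, against 3.26% of the other protein-coding genes (odds ratio 7.31, Fisher's exact test, adjusted p = 2.09e-07). The strongest were rps-23 (signal 405.6, summit at -285 bp), rps-24 (358.3, -565 bp), rpl-15 (267.1, -350 bp) and rps-26 (260.6, -432 bp). The rps-26 summit also lay within 100 bp of a snoRNA gene. When each peak was given only to the gene with the nearest start, 8 of the 81 had a peak and the odds ratio was 3.11 (Fisher's exact test, adjusted p = 0.093). Against genes matched on the distance to the next gene upstream the odds ratio was 4.50 (permutation, adjusted p = 0.005).

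Several lists held no peak or few. No summit fell in the window of any of the 92 homeobox genes (upper 95% bound 3.93%), the 32 bHLH factors, or the lists for intestine (18 genes), epidermis (23), body wall muscle (25), pharynx (13) and neurons (28). The 24 folate genes and the 47 genes of the vacuolar ATPase, lysosome and autophagy list held none either. These lists are small, and the upper bounds of the last 8 ran from 7.55% to 24.7%, so a share equal to the 3.32% of all genes was not excluded for any of the 9. Nuclear hormone receptors (2 of 269), immune effectors (3 of 306) and oxidative and xenobiotic defence genes (1 of 204) had shares of 0.743%, 0.980% and 0.490%, with an adjusted p of 0.102 for each. With a window of 2000 bp upstream, nuclear hormone receptors and immune effectors passed the threshold (Fisher's exact test, adjusted p = 0.0176 for each). Without the peaks at tRNA and snoRNA genes, an alternative added after the data were seen, all 3 passed it, with 4 lists past it in all. That step removed 1 of the few genes with a peak from each of the 3, nhr-255 and clec-126 with a summit near a tRNA gene and gst-27 with one near a snoRNA gene (named after their values were seen).

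Of 29 bZIP factor genes 1 had a peak, cebp-2, which encodes a C/EBP homologue (I, 6252752 to 6253195, signal 207.6, summit at -108 bp). Of 28 endoplasmic reticulum stress genes 2 had a peak, dad-1, which encodes a subunit of the oligosaccharyltransferase complex (211.2), and pdi-6, a protein disulfide isomerase gene (111.1). The remaining lists did not pass the threshold. They were proteasome (3 of 33), lipid metabolism (4 of 96), collagens (3 of 170), histones (2 of 72), germline and maternal (2 of 20), cytosolic chaperones (2 of 24), Wnt and Notch (2 of 40), mitochondrial stress (1 of 17), cell cycle (1 of 29) and neuropeptides and insulins (1 of 140). Of the peaks that both replicate lists held but the optimal set lacked, the strongest in promoter windows were those of exo-1 (95), Y48A6B.3 and fipr-17 (95 for the peak they share), ddx-23 (94.8) and memb-1 (94.8), all just under the weakest optimal peak. There were 1519 such peaks.

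**Figure D3:**
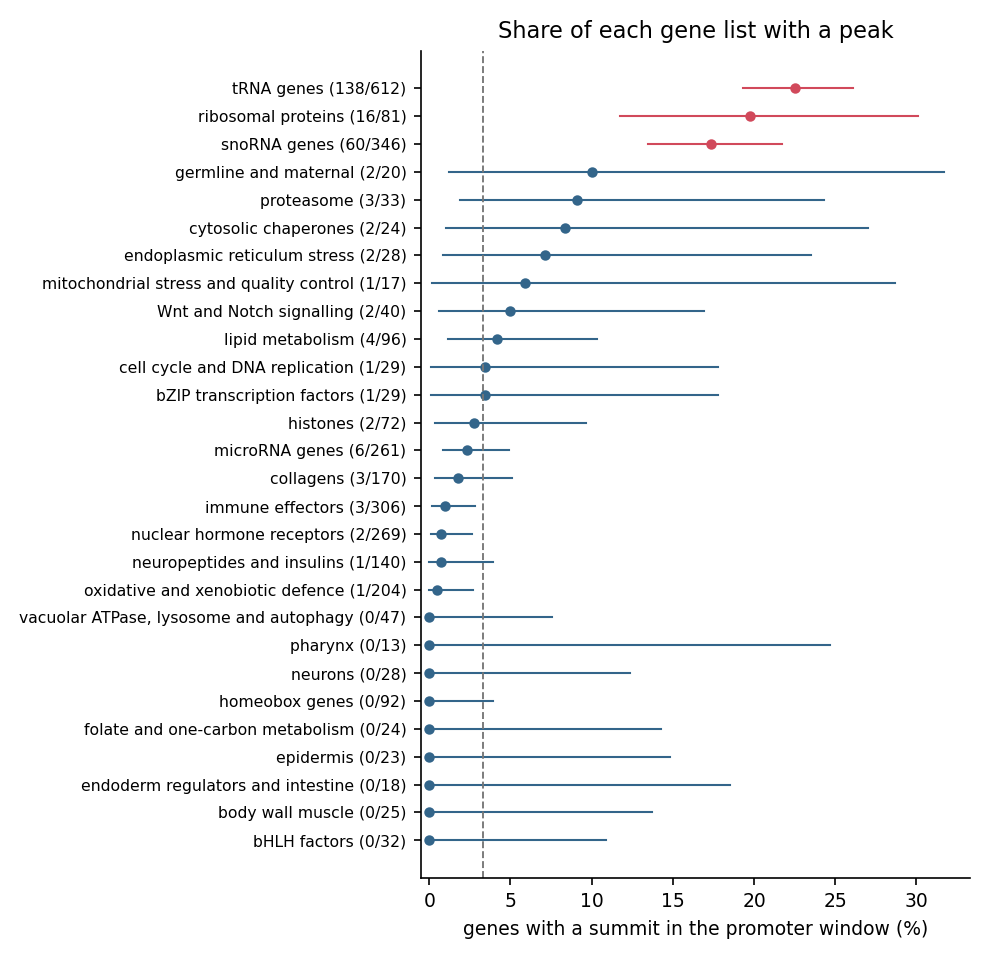
Percent of the genes of each fixed list with a summit in the promoter window (x axis), with exact 95% intervals as lines and the number of genes with a summit over the list size beside each name. Red marks the lists with an adjusted p below 0.05, and the dashed line is the 3.32% of all protein-coding genes. tRNA genes, ribosomal proteins and snoRNA genes stand at 22.5%, 19.8% and 17.3%.

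Genes of short non-coding RNAs were a further large class. A summit lay in the promoter window of 138 of 612 tRNA genes (22.5%, 19.3 to 26.1, odds ratio 13.8 against other genes of all biotypes, Fisher's exact test, adjusted p = 4.86e-93) and of 60 of 346 snoRNA genes (17.3%, 13.5 to 21.8, odds ratio 9.22, adjusted p = 8.03e-34). MicroRNA genes did not differ from other genes by this measure (6 of 261, odds ratio 0.984, Fisher's exact test, adjusted p = 1). Counted by peaks, 120 nuclear summits (16.4%, 13.8 to 19.3) lay within 100 bp of a tRNA gene, against a mean of 1.08 and a maximum of 6 over the shifts. Another 50 (6.85%, 5.13 to 8.93) lay within 100 bp of a snoRNA gene, against a mean of 0.906 and a maximum of 5 (one-sided permutation p = 0.001 for each, the smallest the shifts can give). Of the tRNA summits 54 were in introns, 42 in intergenic sequence and 24 in promoter windows of protein-coding genes. MicroRNA genes had 4 summits within 100 bp against a mean of 0.509 (permutation p = 0.004), and 2 without replicate 1 (permutation p = 0.0959). The snoRNA peaks had a median signal of 212.9 and the tRNA peaks one of 142.9, against 158.7 for the 560 peaks near neither. The strongest snoRNA peak (V, 12303505 to 12303781, signal 644.8) lay over C51F7.4 and C51F7.3 in an intron of frm-7. Peaks at ZK265.10 (I, 8259470 to 8259684, 513.3) and W03C9.9 (II, 11960670 to 11960936, 501.1) came next. The tRNA genes with the strongest peak in the window were WBGene00023221 (signal 383.5, summit at -933 bp, in an intron of pxn-1), WBGene00000308 (368.6), WBGene00023042 (325.1, in an intron of sulp-3) and WBGene00006314 (323.3, in an intron of fli-1). No immunoprecipitation without the tag was used here.

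The sites fixed for testing asked which known recognition sequences lay at the summits. The GC box GGGCGG had the lowest p, at 90 of the 730 summits (12.3%, 10 to 14.9) against 3.42% of flanking windows (exact McNemar test, adjusted p = 1.18e-09). At the 273 summits outside promoters it was not past the threshold (paired ratio 1.77 against 4.33 for all summits, counting only peaks with the site in 1 of the 2 windows, exact test, adjusted p = 0.318). Against shuffles of the same windows that keep their dinucleotides its paired ratio was 2.67 (exact McNemar test, adjusted p = 2.61e-05). The GATA site TGATAA was less frequent at summits (10.1%, 8.04 to 12.6) than in the flanks (18.6%, exact McNemar test, adjusted p = 3.7e-05), but the call was lost in 3 of 9 alternatives. These were the shuffles (paired ratio 0.970 against 0.485, exact test, adjusted p = 1), the stronger 50% of the set (0.524, adjusted p = 0.0623) and summits outside promoters (0.567, adjusted p = 0.0964). Sites of bZIP factors were rare. Any of the 9 fixed bZIP sites lay at 51 summits (6.99%, 5.25 to 9.08) and in 7.40% of the flanks (exact McNemar test, p = 0.842). The cyclic AMP response element TGACGTCA lay at 4 summits and in 4 flanks. The C/EBP site TTGCGCAA lay at 13 summits (1.78%) against 2 flanks (0.274%), a paired ratio of 5.4 with an adjusted p of 0.0468. The wider fixed site TTRCGYAA, which includes it, lay at 15 summits against 4 flanks (exact McNemar test, adjusted p = 0.073). TTACGTAA, also included in the wider site, lay at 0 summits. Counts were small, and the call of TTGCGCAA was lost in 7 of 9 alternatives. Among these the paired ratio stayed high within 50 bp of the summit (5.67, exact test, adjusted p = 0.124) and fell to 3.80 without replicate 2 (0.178), to 2.64 without replicate 1 (0.207), to 2.2 in the stronger 50% of the set (0.959) and to 2.07 within 200 bp (0.318). Against the shuffled windows (1.08) and outside promoters (1) there was little or no enrichment. The call held at promoter summits alone (exact test, adjusted p = 0.00618) and without the tRNA and snoRNA peaks (0.0174). In these sets and at summits outside promoters the control sides were drawn again. A change of call there, for any site, can therefore also come from the control windows.

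The open search found further enriched sequences. Of the 8-mers, 637 were enriched and 56 depleted at summits, and of the 6-mers 404 and 389. Summit windows had a mean GC content of 41.8% and the flanks 36.9%, which these counts do not take into account. CTAGGCCA led the 8-mers, at 85 summits (11.6%) against 8 of 1460 flanking windows (0.548%, odds ratio 23.9, Fisher's exact test, adjusted p = 1.64e-28). Its overlapping words GTGGCCTA, GGCCTAGA and GCCTAGAA were at 66, 62 and 62 summits. Of its 92 occurrences within 100 bp of a summit, 92.4% (84.9 to 96.9) lay within 50 bp, against 52.1% if they were spread evenly. It was concentrated at promoter peaks. Of the 420 promoter peaks away from tRNA and snoRNA genes, 77 had it (18.3%, 14.7 to 22.4), against 2 of the 120 tRNA peaks (1.67%, 0.202 to 5.89) and 2 of the 50 snoRNA peaks (4.0%, 0.488 to 13.7). GGGTTCGA showed the opposite pattern, at 46 of the 120 tRNA peaks (38.3%, 29.6 to 47.6) and 2 of the 420 promoter peaks (0.476%, 0.0577 to 1.71). It lies within the B box, the internal promoter element shared by tRNA genes. Another group of overlapping words, with ACTCCTCT at 51 summits and GGAGTACA at 50, also lay mainly at promoters. Of the depleted 6-mers, CTGAAA had the lowest p, at 21.2% of summits against 42.4% of flanks. The flanks, centred 500 bp away, were not matched on location and can reach into genes, so a depletion may reflect what the flanks hold.

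**Figure D4:**
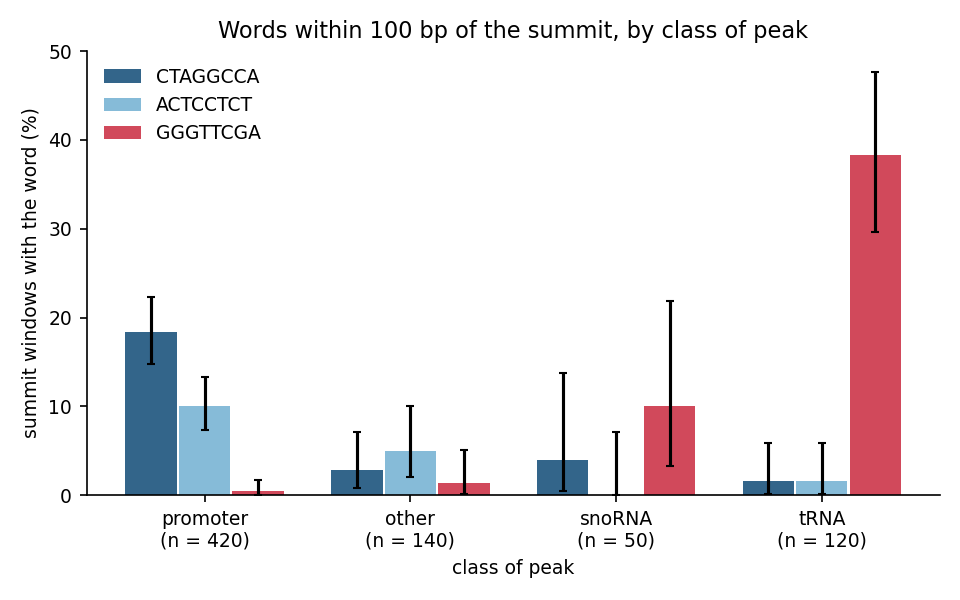
Percent of summit windows that hold CTAGGCCA, ACTCCTCT or GGGTTCGA within 100 bp of the summit (y axis), with exact 95% intervals, for promoter peaks and other peaks away from tRNA and snoRNA genes, snoRNA peaks and tRNA peaks (x axis). CTAGGCCA is at 18.3% of the promoter peaks, and GGGTTCGA at 38.3% of the tRNA peaks.

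Peaks were spread unevenly over the chromosomes. Chromosome III held 10 peaks per Mb and chromosome I 9.35, against 7.92 on II, 6.46 on IV, 5.83 on V and 5.36 on X. Relative to gene number, III and I also led, with 52.3 and 49 peaks per 1000 protein-coding genes, and V was lowest at 24.4. The counts departed from chromosome length (chi-square 40.5) and from gene number (51), with a Monte Carlo permutation p = 1e-05 for each, the smallest the draws can give. Without replicate 1 the value for length was 26.5 (permutation p = 0.00015).

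The strain carries extra copies of zip-5 and a mutation in unc-119, the gene commonly used to select transgenic worms. No optimal summit lay within 20 kb of zip-5 (V, 13264545 to 13269827) or of unc-119 (III, 10902641 to 10908935), and the nearest were 43408 and 45626 bp away. Random windows of the same size held a mean of 0.331 and 0.335 summits and a median of 0. In the replicate lists the zip-5 window held 3 and 3 summits and the unc-119 window 7 and 5, the last pair with a one-sided permutation p of 0.0692 for replicate 1 and 0.252 for replicate 2.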

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

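The mitochondrial chromosome, which the comparisons of genes and sites did not use, held 16 of the 746 optimal peaks on 13.8 kb (2.14%). They were picked out because these peaks entered none of those comparisons, and no expected number was computed. Of the 20 strongest peaks 7 were mitochondrial, led by one with a signal of 1740 (12173 to 12577), and the replicate 1 and replicate 2 lists held 22 and 16 mitochondrial entries. The control libraries were not used here, so their level there was not compared. No explanation of these peaks was tested.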

How the results depend on the processing

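The sets without tRNA and snoRNA peaks, the word counts other than the full set, the nuclear rank correlation, the symbol genes as background for families, and the counts of tRNA and snoRNA summits were alternatives or tests chosen after seeing the data. Over 88 alternatives of the main results, 81 were alike, by direction and side of the threshold where the result has a p, and otherwise by a count within 1.5 times. They included every alternative for overlap, rank correlation, location, chromosomes, peak strength, tRNA and snoRNA summits, and zip-5 and unc-119. The overlap and rank alternatives use the optimal set, which was derived from the replicate lists, so they had little room to differ. The location classes are shares of the same summits, and the zip-5 and unc-119 results were not past the threshold to begin with. The 81 are therefore not independent evidence of stability. The promoter share ran from 54.4% to 75% and the rank correlation from 0.766 to 0.815. The number of gene lists past the threshold rose from 1 to 3 with a window of 2000 bp upstream and to 4 without tRNA and snoRNA peaks. It fell to 0 with the nearest start, by Fisher's exact test (4 lists at an unadjusted p under 0.05). The number of fixed sites past it fell from 3 to 1 in the stronger 50% of the set, and to 1 at summits outside promoters, which was the GA repeat and none of the 3. An equal number did not mean the same sites, since without replicate 1 the C/EBP site was lost and the GA repeat GAGAGAGA gained. The GA repeat (paired ratio 2.52, exact test, adjusted p = 0.0538) passed in 4 of 9 alternatives, without replicate 1 (3.71), without replicate 2 (3.24), against shuffled windows (4.64) and outside promoters (12 summit windows against 0). Outside promoters the control sides were drawn again, which can also move a call. Without tRNA and snoRNA peaks 266 6-mers and 391 8-mers were enriched, against 404 and 637. Of single sites, the PHA-4 site TRTTTRY turned direction within 50 bp of the summit (paired ratio 0.971) and outside promoters (0.901), and the SKN-1 site WWTRTCAT against shuffled windows (1.30), in no case past the threshold. In its first direction the PHA-4 site passed it in 5 of 9 alternatives. The SKN-1 site did so within 200 bp of the summit (paired ratio 0.682, exact test, adjusted p = 0.037). The T tract TTTTTTTT, also less frequent at summits, passed it within 50 bp (0.445, exact test, adjusted p = 0.000989). The C/EBP site stayed past the threshold in 2 of 9 alternatives. Where no cause is named, the cause was not tested. The ce10 lists were run for overlap and rank only. No paired analysis was possible because there is 1 group. Depth is unknown and sets no limit that could be computed here.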

Other observations

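The families, the words by class of peak, the tests of CTAGGCCA, the tests of GC content and gene copies, and the test of bZIP sites at tRNA and snoRNA summits were chosen only after the result was seen. Among 240 families of protein-coding genes that share a symbol and have at least 8 members, 4 had an adjusted p below 0.05 against all other protein-coding genes (Fisher's exact test). These were rps (8 of 31 genes, 25.8%), rpl (8 of 47), sec (5 of 19, 26.3%) and vps (6 of 31, 19.4%). Genes with a symbol had a summit more often than the rest (4.16% against 2.32%). Against the other genes with a symbol only rps of these 4 stayed past the threshold (exact test, adjusted p = 0.00682), and rpl (0.0506), sec (0.0522) and vps (0.056) did not. With that background the 193 str genes, a family of chemoreceptors, passed it with no summit (exact test, adjusted p = 0.049, against 0.119 with all genes).

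An 11-base word made of overlapping enriched 8-mers, GAGGAGTACAC, had 375 copies on the nuclear chromosomes and lay at 39 of the 730 summits (5.34%, 3.83 to 7.23). None of these was among the 120 tRNA peaks or the 50 snoRNA peaks. snRNA genes had 8 summits within 100 bp, against a mean of 0.329 over the shifts.

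Summits at tRNA and snoRNA genes could come from base composition or from reads that fit several gene copies. Positions elsewhere with the GC content of tRNA genes held a summit in 0.294% of cases (0.174 to 0.464). Those matched to snoRNA genes held one in 0.318% (0.159 to 0.568). Of the genes themselves, 20.1% and 14.5% had a summit within 100 bp. These values argue against GC content alone, but the positions were not matched on location relative to protein-coding genes. Reads shared between identical copies are argued against as the whole cause by the 143 tRNA genes with no identical copy. Of these, 9.79% (5.46 to 15.9) held a summit. The snoRNA genes, none of which had an identical copy, held one in 14.5% of cases. Near-identical copies were not searched for, so reads shared with them are not excluded. A part played by identical copies is not excluded either, since tRNA genes with such copies held a summit more often (23.2%, Fisher's exact test, p = 0.000311). In 6.82% (1.43 to 18.7) of the 44 families of identical genes with a summit did every member hold one. This cannot decide the question, since a member can miss the optimal set by strength alone. What also stays open is that open, heavily transcribed loci are recovered by any immunoprecipitation. A fixed bZIP site lay at 4.71% of these 170 summits and in 5.88% of flanks (exact McNemar test, p = 0.804). Such recovery cannot be told apart from binding of ZIP-5 without an immunoprecipitation that lacks the tag. No biological explanation was tested, since the design has 1 group.

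The word CTAGGCCA at promoter summits, found in the open search, was in 79 of 457 promoter summit windows (17.3%, 13.9 to 21.1), while 92 of its 5717 copies on the nuclear chromosomes lay within 100 bp of a summit. Long near-identical copies of a repeat are argued against, since 1.27% (0.032 to 6.85) of the 79 windows had another copy of at least 100 bp at 90% identity. Shorter or more diverged copies were not searched for, so reads shared with them are not excluded. Composition is argued against too, since the highest share over 100 shuffles that keep the dinucleotides was 0.438%. In promoters without an optimal summit, windows at the same distances held the word in 0.744% of cases (0.516 to 1.04). These windows had a mean GC content of 34.5%, against 40.0% at promoter summits, so GC was not matched. Promoters with a peak only outside the optimal set counted as without a summit. Of the 695 promoter windows with the word anywhere 144 (20.7%) had an optimal summit, against 2.70% of those without it. The 79 promoter peaks with the word had a median signal of 184.3. The 378 without it had 162.3, a difference not past the threshold (two-sided permutation p = 0.0731). A hypothesis is that the word may mark a sequence recognised by ZIP-5 or by another protein at these promoters. The word was found and tested on the same data and holds no fixed bZIP site. Recovery of open promoters by any immunoprecipitation was not tested for it. Binding of purified ZIP-5 to the word and to mutated forms of it, and an immunoprecipitation without the tag, would decide the hypothesis.

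Extra copies of the zip-5 transgene could raise the local read density, as could extra copies of an unc-119 rescue fragment around that gene. Each predicts more optimal summits within 20 kb of the gene than 95% of random windows, which hold up to 2. The counts were 0 for zip-5 and 0 for unc-119, equal to the median of random windows, so the optimal set held no excess of summits there. Whether read density was raised cannot be told from this. The peaks were called with a control, which may carry the same extra copies, and the control libraries were not used here. The unc-119 window held 7 summits in the replicate 1 list and 5 in the replicate 2 list (permutation p = 0.0692 and 0.252), so a weaker effect there is not excluded. The extent of the transgene is not given in the sources used here.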
